A study of Mus musculus with 4 samples.

How the data were processed

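Total RNA of 4 mouse samples (Fibroblast, APNL, APNL+AuEMF and Primary neuron, 1 array each) was labelled and hybridised to an Illumina BeadChip. Per the labels, 0.55 ug of total RNA was labelled for each array. The chip, the scan date and the handling of background in the scanner software are not given in the sources used here. The submitters' processing notes name GenomeStudio 2011.1. The deposited non-normalized table holds a probe intensity on a linear scale for each of 25697 probes and 4 arrays, with no normalization between arrays. Beside each intensity the deposited table holds a detection p-value, which compares the probe with the negative control beads of its array and moves in steps of 1 in 798. The authors also deposited a table of log2 values. A quantile normalization of the log2 intensity with no background correction gave these deposited log2 values to within 5e-07, so this is how they were made as far as the values show.

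Main values were computed from the deposited intensity with the neqc function of limma 3.58.1 in R 4.3.3. It subtracts a normexp background whose parameters come from the negative controls, here inferred from the detection p-values, adds an offset of 16, takes log2 and quantile-normalizes the 4 arrays together. A probe counted as detected at a detection p under 0.01. On the 4 arrays, in the order given above, 41.4%, 42.9%, 45.8% and 47.8% of probes were detected, upper quartiles of raw intensity were 678, 722, 896 and 990, and the lowest detected values after normalization were 7.13, 6.93, 6.58 and 6.36. The depth of an array is set by signal over background, and the number of arrays limits the precision. Of the probes 23978 had 1 gene symbol, 0 had several and 1719 had none in the annotation given. By gene identifier 23962 probes matched the reference annotation, and 0 symbols needed an update. A gene was represented by its probe with the highest mean value over the 4 arrays, which gave 16593 genes, of which 4777 had over 1 probe and 9184 were detected on at least 1 array. Genome positions of the probes were not available.

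Groups are the sample titles, and 6 comparisons were made between pairs of arrays. A gene was compared when detected on at least 1 of the 2 arrays. Where it was detected on only 1, the difference was taken against the higher of the other array's lowest detected value and the gene's own value there, which gives a lower bound. A gene counted as higher or lower at 2-fold or more. No p-value, standard error or test of a difference between groups was computed, because each group has 1 array. Bootstrap intervals in the closing section resample genes, which are not independent replicates. Where undetected levels were set against a contrast of neuron shares, they took the end of the range from the array's lowest value to its lowest detected value that made the contrast smallest. Lists of marker and pathway genes, 39 in all with 921 genes of which 813 had a probe, were written before the data were examined. For each list the median log2 difference was taken over members detected on at least 1 of the 2 arrays, with undetected members at their measured values, and again with these at their bounds. The first median was placed as a percentile among 10000 random lists of the same size, matched in 20 bins of mean expression. Sets of neuron-high and fibroblast-high genes were at least 4-fold apart between those 2 arrays.

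Genes are named by a rule fixed before the data were examined. It takes, for each comparison, the reprogramming factors, the 6 largest differences in each direction among genes detected on both arrays, the 4 largest bounds in each direction among genes detected on 1 array, and up to 4 members with the largest absolute difference from each list described. Genes named outside it are marked as chosen after their values were seen, except where a value of a gene so named is given for another array or comparison. Unnamed gene models and control probes were passed over.

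Each result was recomputed under alternatives, each altering 1 choice where possible. The normexp alternative altered the offset and the control information together, no background correction also dropped the offset, and no filter also dropped the bounds. The alternatives were no background correction, normexp with an offset of 50 and no control information, scaling to a common median in place of quantile normalization, the authors' deposited log2 values, detection p under 0.05, detection on both arrays, no filter and no bounds, the mean of a gene's probes, a 3-fold threshold and sets at 8-fold. All were chosen before the data were examined. A count, a median or a value of a single gene counted as moved when it differed by over 1.5-fold. A share counted as moved when it left the 95% Wilson interval of its main value, an interval over genes. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

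The steps were tested on simulated data, with raw signals drawn for an unchanged APNL array and known folds added to some genes. Genes raised 2-fold were called higher in 16 of 34 cases (47.1%), those raised 4-fold in 34 of 34 and those raised 8-fold in 33 of 33. Genes lowered 2-fold were called in 11 of 33 cases (33.3%), 4-fold in 29 of 33 (87.9%) and 8-fold in 31 of 33 (93.9%). None was called the wrong way, and 5 of 7894 unchanged genes reached 2-fold. A list of 30 genes raised 1.5-fold lay at percentile 100, and 8 of 100 lists of unchanged genes fell outside percentiles 5 to 95. Among genes with several detected probes the median range between probes was 0.35 for primary neurons against fibroblasts, 0.15 for APNL, 0.20 for APNL+AuEMF against fibroblasts and 0.21 for APNL+AuEMF against APNL. Probes of 1 gene reached 2-fold in opposite directions for 6, 0, 0 and 0 genes in these comparisons.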

Results

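Gene expression was measured on 4 Illumina BeadChip arrays hybridised with labelled total RNA from mouse cells, 1 array for each of the groups Fibroblast, APNL, APNL+AuEMF and Primary neuron. The series concerns turning cells directly into dopamine neurons with the help of an electromagnetic field. The labels do not spell out APNL or AuEMF. From general knowledge of published work, APNL is taken to stand for a set of introduced transcription factors, and AuEMF for gold nanoparticles in an electromagnetic field. The labels also do not say where the primary neurons came from or how long the cells were cultured. Each array carried 25697 probes, and detected probes numbered 10643 on the fibroblast array, 11030 on APNL, 11776 on APNL+AuEMF and 12287 on the primary neuron array. The median raw signal was 169, 174, 192 and 207 intensity units in the same order. With 1 array per group, no difference below has a replicate check, and the number of arrays limits the precision. All differences are on the log2 scale unless given as folds, and a gene counts as higher or lower at 2-fold or more. Where a gene was detected on only 1 of the compared arrays, its difference is a lower bound set by the lowest detected value of the other array, and is written as at least so many fold.

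The comparison of primary neurons with fibroblasts sets the scale for the others. Most measured genes on the pan-neuronal, synaptic, GABAergic and glutamatergic lists were higher on the primary neuron array, and most genes on the muscle, fibroblast identity and extracellular matrix lists were lower. Nsg2, a neuronal endosome protein gene, was higher by 6.37, Cplx1, which encodes a complexin of synaptic release, by 6.21, Mapt, which encodes tau, by 5.76, and Dcx, the doublecortin gene of young neurons, by 5.68. Higher genes of the interferon response and inflammatory cytokine lists were, among others, Ifit3 by 6.33, Cxcl1 by 5.78 and Cxcl10 by at least 75.5-fold. Myl1, a muscle myosin light chain gene, differed by -7.14, Eln, which encodes elastin, by -5.25, and Actc1, cardiac actin, was at least 83.1-fold lower. In total 991 of 8987 compared genes were higher and 1337 were lower, 42.6% higher, and with scaling in place of quantile normalization 1184 were higher and 1091 lower, 52.0% higher. At a 3-fold threshold 556 were higher and 485 lower.

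Of 34 measured genes on the pan-neuronal list, 29 were higher in primary neurons, 2 were lower and 3 were neither. The median difference was 4.30, or 3.45 with undetected levels set at their bounds. All 7 measured genes on the GABAergic list (inhibitory neurons) were higher, with the neuropeptide gene Sst at 5.61 and the GABA synthesis gene Gad1 at least 33.1-fold. On the glutamatergic list (excitatory neurons) 7 of 9 were higher and 2 neither, including the cortical transcription factor genes Tbr1, at least 14.9-fold, and Neurod2, at least 9.08-fold. Among 20 synaptic genes 14 were higher and 6 neither, with Cadps at 4.86 and Syp, synaptophysin, at 4.63. The interferon response list had 20 genes higher, 1 lower and 11 neither of 32, and the inflammatory cytokine list 15 higher, 3 lower and 7 neither of 25. The astrocyte list had 3 higher and 7 neither of 10, including Aldoc at 3.49. Hba-a1, a haemoglobin gene, had a level of 11.24 on the primary neuron array and was not detected on the other arrays, and Ttr, transthyretin, was at least 53.7-fold higher than in fibroblasts.

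On the lower side, 14 of 15 measured skeletal muscle genes were lower in primary neurons and 1 was neither, with a median of -3.45. The fibroblast array itself carried this muscle signal, for example Myl1 at 13.54 and Myl4 at 13.15. The fibroblast identity list had 22 lower and 9 neither of 31, with Mfap4 at -3.88 and Pdgfra, a growth factor receptor gene, at -3.56. The extracellular matrix list had 24 lower, 2 higher and 11 neither of 37, with Col5a2, a collagen gene, at -2.98. Fibroblast genes were nonetheless present on the primary neuron array: 29 of the 31 fibroblast identity genes detected in fibroblasts were detected there too, at a median of 38.8% of the fibroblast level. For the extracellular matrix list this was 36 of 37 genes at 45.5%. Of 35 cell cycle genes 6 were lower and 29 neither, with a median of -0.49 and Plk1, a mitotic kinase gene, at -1.42. Cholesterol synthesis genes were lower in 7 of 15 and neither in 8, with Nsdhl at -2.02 and Lss, lanosterol synthase, at -1.89. Among these medians, those of the pan-neuronal, synaptic, GABAergic, interferon and inflammatory lists lay at percentile 100 among 10000 random gene lists matched on size and expression, and those of the muscle, fibroblast identity and matrix lists at percentile 0, as a description of these arrays. Without background correction 801 genes were higher and 872 lower.

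The comparison of APNL with fibroblasts concerns the sample taken to hold the factors without the field. The labels name no control for gene delivery or time in culture, so its differences cannot be assigned to the factors themselves. Members of the pan-neuronal, interferon and inflammatory cytokine lists were among the genes higher on the APNL array, and no gene was lower. Ifit3, an interferon-induced gene, was higher by 4.44, the chemokine gene Cxcl1 by 4.14, Cplx1 by 3.45, Sst by 3.37, Rsad2, an antiviral enzyme gene, by 3.29 and Nsg2 by 2.94. Saa3, an acute-phase protein gene, was at least 10.9-fold higher, Cxcl10 at least 9.10-fold, Mpped1 at least 8.50-fold and Gad1 at least 6.73-fold. Of 8242 compared genes 128 were higher and 0 lower. The most negative differences among genes detected on both arrays were those of Washc1 at -0.84 and Rbm10 at -0.79. Of the 128 higher genes, 127 were also at least 4-fold higher in primary neurons than in fibroblasts, and all 128 at least 2-fold. Both differences use the same fibroblast array, so part of this overlap can come from that array. Of the 398 genes at least 4-fold higher in primary neurons, 356 were detected in APNL or fibroblasts. Of these 356 genes 127, or 35.7%, reached 2-fold in APNL, and the rest of the 398 were left out of this share. A simulation of unchanged arrays gave 0%, but it holds array noise alone (SD 0.0903 log2 per array) and no variation between cultures.

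On the pan-neuronal list 12 of 29 measured genes were higher in APNL and 17 neither, with a median of 1.22, or 0.51 with undetected levels at their bounds. Scg5, a secretory granule gene, was higher by 2.64, Mapt by 2.40 and Gpm6a, a neuronal membrane protein gene, by at least 5.33-fold. The synaptic list had 5 higher and 12 neither of 17, with Camk2b at 2.20 and Cadps at 2.04. The GABAergic list had 5 higher and 2 neither of 7, with a median of 1.60, or 1.14 at bounds, including Slc32a1, the vesicular GABA transporter gene, at least 2.98-fold. None of the 5 measured glutamatergic genes was higher, and their median was 0.66, or 0.21 at bounds. The interferon response list had 12 higher and 12 neither of 24, with a median of 1.20, or 1.07 at bounds, and Gbp3 at 2.04. The inflammatory cytokine list had 7 higher and 14 neither of 21, with a median of 0.65, or 0.49 at bounds, Cxcl5 at 2.82 and Ccl5 at 1.72. Olig1, a gene of oligodendrocyte precursors, was higher by 2.07, while 6 of the 7 measured genes of its list were neither.

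Genes of the starting cell differed little between APNL and fibroblasts. The 31 fibroblast identity genes, the 15 skeletal muscle genes and the 34 cell cycle genes had none higher or lower, with medians of -0.11, -0.12 and -0.09. Of 37 extracellular matrix genes 36 were neither and 1 was higher, the matrix protease gene Mmp3 at 1.22. These small medians lay low among random lists, at percentiles 0, 1.85, 0.27 and 0.08 for the fibroblast, muscle, cell cycle and matrix lists. Cholesterol synthesis genes had a median of -0.21 at percentile 0, with Lss at -0.37 and 15 of 15 neither. None of the 10 measured microglia and macrophage genes was higher or lower, with a median of -0.12, and of 7 astrocyte genes 1 was higher and 6 neither, with a median of 0.10. The count of higher genes was 78 without background correction, 77 when detection on both arrays was asked for and 286 with no filter. The last of these also had 35 lower genes, and the pan-neuronal median was 0.42 when detection on both arrays was asked for.

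The comparison of APNL+AuEMF with fibroblasts concerns the sample taken to hold the factors with gold and field, with the same lack of controls. The 128 genes that were higher in APNL were higher here too, most measured macrophage list genes were higher, and 9 of 15 muscle list genes were lower. Ifit3 was higher by 5.93, Cxcl1 by 5.63, Mmp3 by 5.42, Sst by 4.78, Cplx1 by 4.76 and Rsad2 by 4.63. Saa3 was at least 297-fold higher, Cxcl10 at least 36.1-fold, Lcn2, the lipocalin gene of the acute-phase response, at least 35.1-fold and Fcer1g, a receptor subunit gene of myeloid cells, at least 30.8-fold. Gng12 differed by -1.69, Popdc2, a gene of striated muscle, by -1.56, and Chrng, the fetal muscle acetylcholine receptor subunit, by -1.55. Pcdh18 was at least 2.76-fold lower. Of 8675 compared genes 453 were higher and 146 lower.

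All 128 genes higher in APNL were also among the higher genes of APNL+AuEMF, where 6.62 would be shared if the calls were independent. Both comparisons use the same fibroblast array, so part of the excess can come from it. The 0 genes shared in a simulation with no effect cover array noise alone and not variation between cultures. Of the 453 higher genes, 289 were at least 4-fold and 373 at least 2-fold higher in primary neurons than in fibroblasts, again by the same fibroblast array. Of the 398 genes at least 4-fold higher in primary neurons, 396 could be compared here, and 289 of these 396, or 73.0%, were at least 2-fold higher in APNL+AuEMF. On the pan-neuronal list 20 of 34 were higher and 14 neither, with a median of 2.28, or 1.12 with undetected levels at their bounds, including Nsg2 at 4.44 and Mapt at 3.80. The synaptic list had 8 higher and 10 neither of 18, with Syp at 2.94. The GABAergic list had 6 higher and 1 neither of 7, with a median of 3.03, or 2.54 at bounds, and the glutamatergic list 2 higher and 5 neither of 7, with a median of 1.42, or 0.56 at bounds. Gad1 was at least 17.2-fold higher and Tbr1 at least 2.07-fold. The interferon response list had 19 higher and 9 neither of 28, with a median of 2.29, or 1.98 at bounds, and Gbp3 at 3.45. The inflammatory cytokine list had 16 higher and 9 neither of 25, with a median of 2.19, or 1.51 at bounds, and Cxcl5 at 4.62. The astrocyte list had 3 higher and 6 neither of 9, with Aldoc at 2.63.

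The microglia and macrophage list had 8 of 12 measured genes higher than in fibroblasts and 4 neither, with Lyz2, a lysozyme gene, at 2.94, Adgre1, the F4/80 macrophage marker, at 2.41 and the complement gene C1qb at 1.63. These stood beside the acute-phase genes Saa3 and Lcn2 named above. The skeletal muscle list had 9 lower and 6 neither of 15, with a median of -1.01, Casq2 at -1.36 and Tnnc2 at -1.35. Fibroblast identity genes were neither in 27 of 31, with the dermatopontin gene Dpt at 1.45 and Dcn, decorin, at 1.06 among the 2 higher, and Foxd1 at -1.20 and Meox1 at -1.15 as the 2 lower. Extracellular matrix genes were neither in 34 of 37, with the 3 higher genes Mmp3, Mmp13 at 1.91 and Dcn. The 35 cell cycle genes had none higher or lower and a median of -0.27, at percentile 0.19. The metallothionein and oxidative stress list had 5 higher and 14 neither of 19, with the detoxifying enzyme gene Nqo1 at 2.03 and Mt2 at 1.75. Wnt and Notch genes were lower in 3 of 17 and neither in 14, including the Notch ligand gene Jag1 at -1.13. The split of 453 higher and 146 lower genes, 75.6% higher, was 562 and 67 (89.3%) with scaling in place of quantile normalization, 324 and 18 (94.7%) without background correction and 368 and 37 (90.9%) with normexp fitted without control information and with an offset of 50. The pan-neuronal median was 1.31 without background correction, 1.55 with that normexp fit, 1.26 for the mean of a gene's probes and 1.05 when detection on both arrays was asked for.

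**Figure D1:**
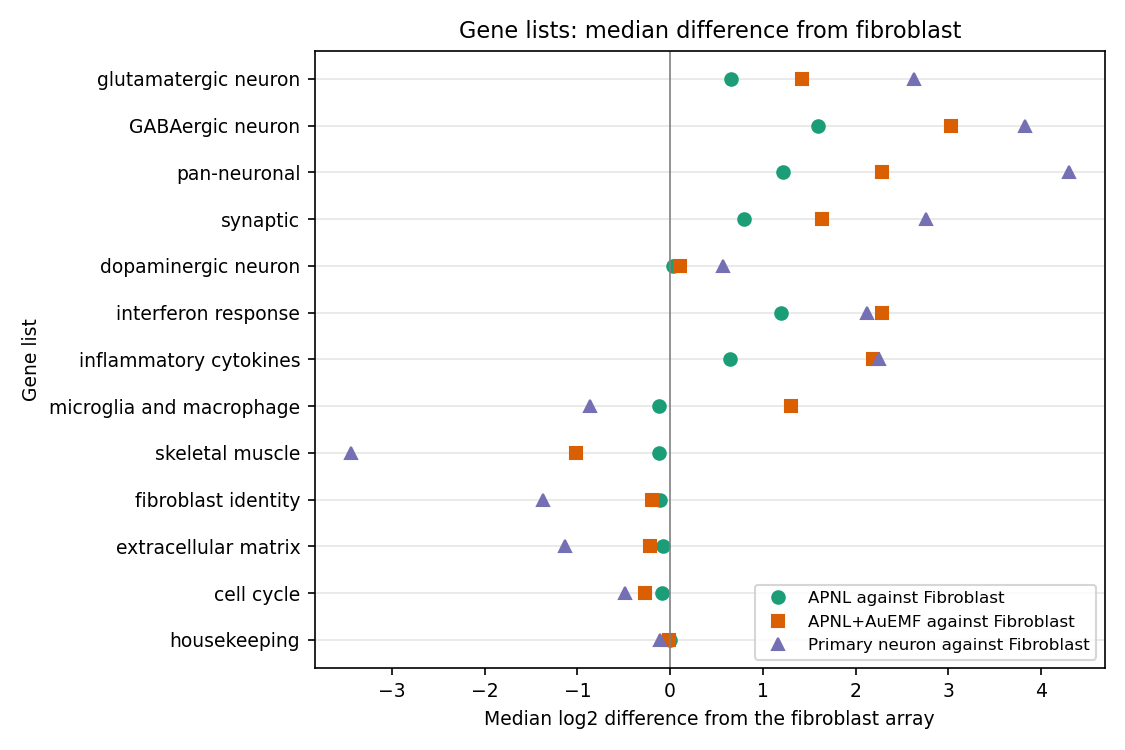
Median log2 difference from the fibroblast array (x axis) of the measured members of 13 gene lists (y axis) for APNL, APNL+AuEMF and Primary neuron, 1 array each. The pan-neuronal medians are 1.22, 2.28 and 4.30, the microglia and macrophage medians -0.12, 1.30 and -0.87.

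The comparison of APNL+AuEMF with APNL addresses the step that the series title is about, the addition of AuEMF. The genes with the largest differences were higher with AuEMF, and the medians of the macrophage, pan-neuronal and interferon lists were above 0. Lcn2 was higher by 5.01, Saa3 by 4.77, Mmp3 by 4.21, the eosinophil chemokine gene Ccl11 by 4.05, Serpina3n, an acute-phase protease inhibitor gene, by 3.78 and Clec4d, a myeloid lectin gene, by 3.26. Fcer1g was at least 35.4-fold higher, the chemokine gene Ccl8 at least 12.5-fold, Sspn at least 9.55-fold and Mmp12, macrophage elastase, at least 9.53-fold. The lowest differences were smaller, with Adamts19 at -1.33, Map3k7cl and Chrng both at -1.32, and Omd, osteomodulin, at -1.27. Pcdh18 was at least 2.31-fold lower, and Heyl, a Notch target gene, at least 2.20-fold. In total 273 of 8700 compared genes were higher and 66 lower.

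On the pan-neuronal list 15 of 34 measured genes were higher with AuEMF and 19 neither, with a median of 1.08. Nsg2 was higher by 1.49, Stmn3 by 1.45 and Mapt by 1.41. The synaptic list had 5 higher and 14 neither of 19, with Syp at 1.41. The GABAergic list had 5 higher and 2 neither of 7, with the interneuron genes Calb2 at 1.43, Sst at 1.42 and Npy at 1.40. None of the 7 glutamatergic genes was higher, with Nrn1 at 0.90 and Tbr1 at 0.85. The interferon response list had 15 higher and 13 neither of 28, with a median of 1.19, including the transcription factor gene Irf7 at 1.85 and Isg15 at 1.80. The inflammatory cytokine list had 10 higher and 15 neither of 25, with a median of 1.00. All of these medians lay at percentile 100 except that of the glutamatergic list, at 99.8.

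Beside these groups, 8 of 12 microglia and macrophage genes were higher with AuEMF and 4 neither, with a median of 1.39. Lyz2 was higher by 3.05, Adgre1 by 2.55 and the myeloid adaptor gene Tyrobp by 1.91. Cx3cr1 and Tmem119, microglia genes chosen for mention after their values were seen, went the other way, with differences of -0.96 and -0.47. Both were already present in fibroblasts, at 8.25 and 11.46. Of the 26 genes at least 4-fold higher than in APNL, 23 were also at least 2-fold higher than in primary neurons. Over all genes, 62 were at least 2-fold above both fibroblasts and primary neurons in APNL+AuEMF, against 0 in APNL.

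Muscle genes were lower with AuEMF in 4 of 15 and neither in 11, with a median of -0.89 and Casq2 at -1.13. The fibroblast identity list had 2 higher and 29 neither of 31, with Dpt at 1.58 and Dcn at 1.26, and a median of -0.08 at percentile 28.5. The matrix list had 3 higher and 34 neither of 37, with a median of -0.04 at percentile 49.3. Of 35 cell cycle genes 1 was lower, the mitotic ubiquitin conjugation gene Ube2c at -1.20, and 34 were neither, with a median of -0.24 at percentile 0.04. The cell cycle inhibitor gene Cdkn2a was higher by 1.53, and Pcna, a DNA replication gene, differed by -0.80. Histone acetylation genes, the enzymes that add or remove acetyl groups on histones, were neither in 21 of 21, with a median of -0.06, and Ep300 at -0.62 and Kat2a at 0.46. Cholesterol synthesis genes were neither in 15 of 15, with a median of -0.34 at percentile 0.05 and Nsdhl at -0.82.

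Of the 398 genes at least 4-fold higher in primary neurons than in fibroblasts, 396 could be compared between APNL+AuEMF and APNL. The 4-fold cut used neither of these arrays, although all 4 arrays entered the normalization and the choice of probe per gene. With AuEMF 165 of them, 41.7%, were at least 2-fold higher, 390 were higher by any amount, and the median difference was 0.99. Of the 272 genes at least 4-fold higher in fibroblasts, 29 or 10.7% were at least 2-fold lower with AuEMF, 255 were lower by any amount, and the median was -0.62. Across 8503 genes, which are not independent replicates, the neuron minus fibroblast difference and the APNL+AuEMF minus APNL difference had Pearson r 0.730 and Spearman rho 0.741. The split of 273 higher and 66 lower genes, 80.5% higher, was 375 and 16 (95.9%) with scaling, 146 and 0 without background correction and 184 and 4 (97.9%) with normexp fitted without control information and with an offset of 50. Under these 3 settings the shares were 51.7% and 5.79%, 29.0% and 0%, and 33.6% and 0.685%.

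**Figure D2:**
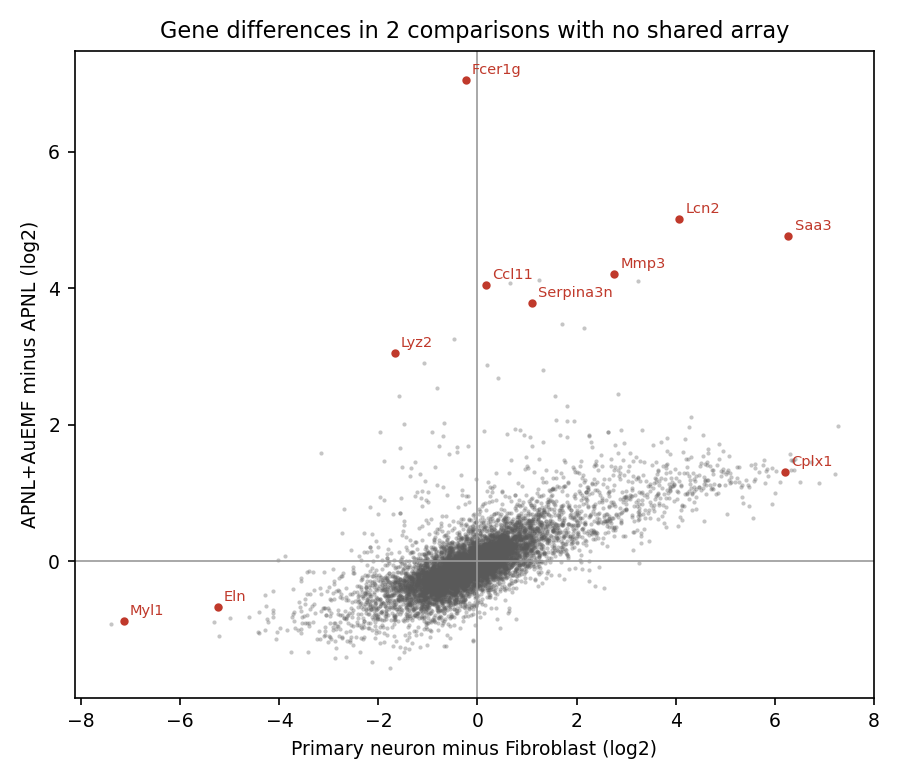
Measured log2 differences between primary neurons and fibroblasts (x axis) and between APNL+AuEMF and APNL (y axis), 1 point for each of 8503 genes. Most points follow a rising band (Pearson r 0.730), while Fcer1g, Lcn2, Saa3, Mmp3, Ccl11, Serpina3n and Lyz2 lie above it.

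Compared with primary neurons, a measure of the distance left to the reference cell, both APNL samples had positive medians of the muscle and fibroblast identity lists and negative medians of the pan-neuronal list. These medians lay nearer to 0 for APNL+AuEMF. Myl1 was higher by 6.95 in APNL and by 6.08 in APNL+AuEMF, and Eln by 4.97 and 4.31. Actc1 was at least 71.2-fold and at least 37.9-fold higher. Islr2, a neuronal membrane protein gene, was at least 24.9-fold lower in APNL and differed by -3.50 in APNL+AuEMF. Tfap2c differed by -4.16 and -3.30, and Hba-a1 was at least 19.8-fold and at least 25.2-fold lower. In APNL 1141 of 9010 compared genes were higher and 962 lower than in primary neurons, and in APNL+AuEMF 673 of 9076 were higher and 612 lower. Pearson r with the primary neuron array across 9184 genes was 0.852 for fibroblasts, 0.896 for APNL and 0.939 for APNL+AuEMF.

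The pan-neuronal list had 29 of 34 genes lower than in primary neurons, 1 higher and 4 neither in each of the APNL samples, with medians of -2.73 in APNL and -1.74 in APNL+AuEMF. Crmp1, an axon growth gene, differed by -3.86 and -2.57, and Elavl3, a neuronal RNA-binding protein gene, by -3.77 and -2.67. Of 9 glutamatergic genes 7 were lower in each, with medians of -2.50 and -2.18. Tbr1 differed by -3.69 and -2.84. Of 7 GABAergic genes all 7 were lower in APNL, with a median of -2.25, and 3 in APNL+AuEMF, with a median of -0.95. Gad1 differed by -2.30 and -0.95. The interferon list had 19 lower, 1 higher and 12 neither of 32 in APNL, and 2 lower, 1 higher and 29 neither in APNL+AuEMF. Its medians were -1.43 and -0.31. The inflammatory list had a median of -1.02 in APNL and -0.02 in APNL+AuEMF, the latter 0.12 with scaling in place of quantile normalization. Of its 25 genes, 3 were higher, 11 lower and 11 neither in APNL, and 6 were higher, 1 lower and 18 neither in APNL+AuEMF, with Ccl8 at 3.66, Lcn2 at 3.21 and Saa3 at 2.46 among the higher ones.

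Macrophage genes set APNL+AuEMF apart from primary neurons as well, with 9 of 12 higher and 3 neither, a median of 2.08, Fcer1g at least 52.4-fold, Lyz2 at 4.61 and Adgre1 at 3.24. In APNL 3 of 10 were higher, with Tmem119 at 3.18. The muscle list had 14 of 15 higher in APNL and 9 of 15 in APNL+AuEMF, with medians of 3.27 and 2.26. Fibroblast identity genes were higher in 19 and 18 of 31, with Mfap4 at 3.65 and 3.74. Matrix genes were higher in 20 and 18 of 37, with the hydroxylase gene P4ha1 at 3.21 and 2.73. Of 35 cell cycle genes 4 were higher and 1 lower in APNL, and of 34 none was higher or lower in APNL+AuEMF. The balance of higher and lower genes turned with scaling in place of quantile normalization, to 972 higher and 1141 lower in APNL and 577 higher and 689 lower in APNL+AuEMF. At a 3-fold threshold it turned in APNL, with 409 higher and 472 lower, and not in APNL+AuEMF, with 257 and 217. Without background correction the counts were 732 higher and 736 lower in APNL and 433 higher and 435 lower in APNL+AuEMF.

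**Figure D3:**
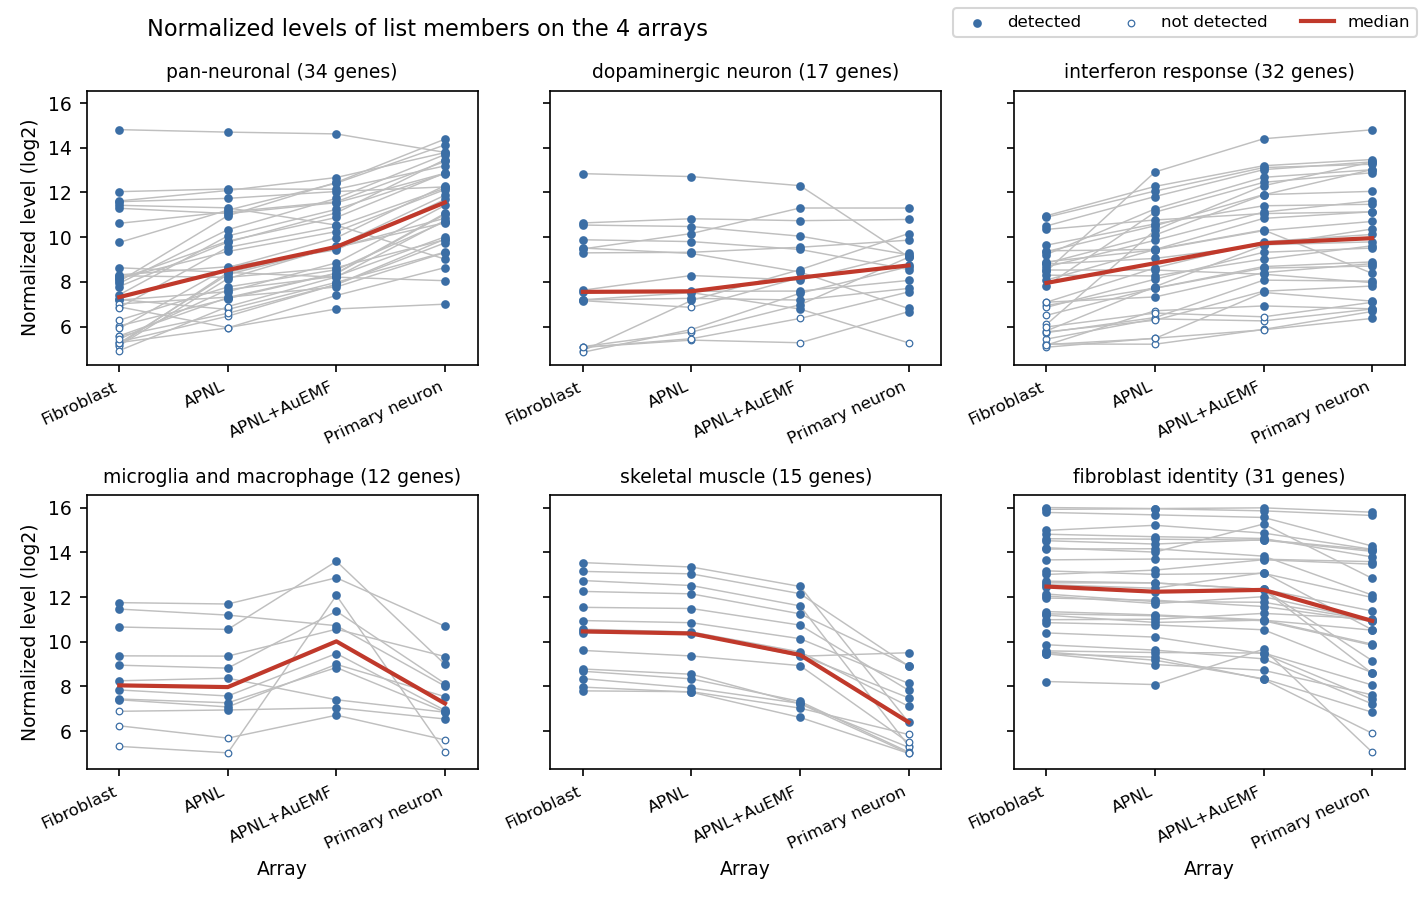
Normalized log2 levels (y axis) of the members of 6 gene lists on the 4 arrays (x axis), 1 line per gene, with filled points for detected values, open points for undetected ones and a thick line for the median. Of 34 pan-neuronal genes 26 are ordered Fibroblast, APNL, APNL+AuEMF, Primary neuron from low to high, and 14 of 15 muscle genes the other way.

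The reprogramming factors and the dopamine neuron genes are the items the series title is about. The reprogramming factor genes described here are Pitx3, Nr4a2 and Lmx1a. Pitx3 was not detected on any array, with values of 5.08 in fibroblasts, 5.56 in APNL, 5.16 in APNL+AuEMF and 5.19 in primary neurons. Lmx1a was detected in primary neurons alone, at 6.67. That level lies below the lowest detected values in fibroblasts (7.13) and APNL (6.93) and near that of APNL+AuEMF (6.58). Its detection on 1 array therefore does not show a higher level there. Nr4a2 was at 7.19, 7.26, 7.19 and 7.71 in the same order. Whether these probes lie in sequence carried by an introduced copy of the genes is unknown, since probe positions were not available. Th, the rate-limiting enzyme of dopamine synthesis, Slc6a3, the dopamine transporter gene, and Slc18a2, the vesicular monoamine transporter gene, were chosen for mention after their values were seen. None of these 3 was detected on any array, and Th was at 5.09, 5.02, 5.15 and 5.48.

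Of 13 dopaminergic list genes measured in APNL against fibroblasts, all were neither, with a median of 0.03 at percentile 68.9, Gch1 at 0.69 and Chrna4 at 0.66. In APNL+AuEMF against fibroblasts 3 of 15 were higher, 1 lower and 11 neither, with a median of 0.10 at percentile 80.6. Gch1, which makes the cofactor of tyrosine hydroxylase and of nitric oxide synthases, was higher by 1.83 and Sncg, a synuclein gene, by 1.03. Otx2, a transcription factor gene of the fore- and midbrain, was at least 2.67-fold higher. Ddc, the decarboxylase of dopamine and serotonin synthesis, differed by -1.07. In APNL+AuEMF against APNL 3 of 15 were higher and 12 neither, namely Otx2 by 1.38, Gch1 by 1.14 and Sncg by at least 2.39-fold. The median of that comparison was -0.08 at percentile 42.0, and turned to 0.14 with scaling and 0.01 for the mean of a gene's probes. Primary neurons had 6 of 17 higher and 4 lower than fibroblasts, with Otx2 at least 8.18-fold and En2, a midbrain transcription factor gene, at least 3.92-fold higher, and Dlk1 at -3.73 and Ddc at -2.70. Their median was 0.57 at percentile 96.1. Gch1 stood at 9.47, 10.16, 11.31 and 11.30 in fibroblasts, APNL, APNL+AuEMF and primary neurons.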

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

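For the patterns weighed here, the tests on list contrasts, on another brain culture and on macrophage genes were chosen only after the result was seen, and the tests on probe pairs and on normalization before it, although shares of a few genes had been looked at by then. Probes without a gene symbol (1719 in all) took no part in the comparisons and gave a signal above the fibroblast array: 25 were at least 4-fold higher in primary neurons, 1 in APNL and 3 in APNL+AuEMF.

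In APNL, genes that are high in primary neurons lay between the fibroblast and the primary neuron array, at a median share of 10.4% of the neuron signal over 398 genes. RNA or cells of the primary neuron sample mixed in at a single fraction, with no other change, would give every gene the same share. Interferon and cytokine genes had a median share of 25.1% (24 genes, all detected in APNL) and neuronal lists 8.02% (49 genes). The log2 difference was 1.65 (95% bootstrap interval 1.22 to 1.91), or 1.20 (0.85 to 1.58) with undetected levels set against it. GABAergic genes had 15.3% and glutamatergic genes 5.70%, a difference of 1.43 (0.62 to 2.55, 7 genes each), but 2 of these glutamatergic genes were not detected in APNL, and with undetected levels set against it the difference was 0.43 (0.11 to 1.54). The test fixed beforehand, the correlation of shares between 2 probes of 1 gene, gave r 0.633 over 26 genes. Its interval of 0.0691 to 0.853 was too wide for the bound set in advance, so the argument rests on the list contrasts. The interferon and cytokine contrast argues against a single fraction as the only change. It cannot decide for the neuronal genes, since interferon and cytokine genes could also rise in the treated cells. For neuronal genes the argument rests on the GABAergic and glutamatergic lists, 7 genes each. Shares of the 7 GABAergic genes, looked at after the contrast was seen, were uneven. Slc32a1 (9.47%), Dlx2 (11.2%) and Dlx1 (11.9%) lay near the median of 10.4% over the 398 genes. Calb2 (15.3%), Gad1 (18.9%), Sst (19.4%) and Npy (25.6%) lay above it. RNA or cells of another brain culture, richer in some interneuron transcripts and in interferon and cytokine transcripts, remains a candidate source. Shares ranked alike in APNL and APNL+AuEMF with Spearman rho 0.880, against a simulated median of 0.32 for a single fraction. Conversion of the fibroblasts by the factors, the explanation the design names, could also give a shared ranking. No ranking under conversion was simulated, and conversion was not tested apart from another brain culture.

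In APNL+AuEMF the same genes had a median share of 27.1%, and 390 of 396 were above APNL. Quantile normalization of arrays of different brightness is argued against, since the median difference from APNL was 1.09 with scaling alone. Shares correlated between 2 probes of 1 gene with r 0.856 over 38 genes (interval 0.553 to 0.951), where a simulated mixture of 25% gave 0.16. This argues against a single fraction of the primary neuron sample as the only change. It cannot decide for neuronal genes, since interferon and cytokine genes (median share 78.6%, neuronal lists 23.3%) were not set apart. GABAergic genes had 51.0% and glutamatergic genes 12.9%, a difference of 1.98 (0.78 to 2.35, 7 genes each). With undetected levels set against it the difference was 1.75 (0.63 to 2.11), which argues against a single fraction for these genes. Here too the GABAergic shares were uneven, with Dlx2 at 20.2%, Slc32a1 at 26.0% and Dlx1 at 30.3%, against the median of 27.1%. Gad1 (51.0%), Calb2 (54.2%), Sst (55.5%) and Npy (103%) lay well above it. Simulated mixtures gave 126 genes higher and 7 lower than fibroblasts at 10%, where APNL had 128 and 0. At 25% they gave 327 and 60, where APNL+AuEMF had 453 and 146. The simulated fractions lie near the observed median shares of 10.4% and 27.1%, so similar counts of higher genes are partly built in. These simulations held array noise alone (SD 0.1 log2), and no counts under conversion were simulated. The counts therefore do not decide between mixing and conversion. A larger part of another brain culture than in APNL, and conversion helped by gold and field, both remain open as hypotheses.

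On the APNL+AuEMF array macrophage genes and the acute-phase protein genes Saa3, Lcn2 and Serpina3n were high. Of 12 measured macrophage genes 8, 66.7%, were at least 2-fold above APNL, with the lysozyme gene Lyz2 at 13.60 and Fcer1g at 12.07, while Cx3cr1 differed by -0.96 and Tmem119 by -0.47, short of 2-fold, and 9 of the 12 were detected in fibroblasts as well. That share restates the pattern, so it does not show macrophages to be the source, and they stay open, as the labels name no sort that would remove them. The primary neuron culture is argued against as the source, since 88.5% of the genes at least 4-fold above APNL (23 of 26) exceeded the primary neuron array by 2-fold or more. A response of the cells to gold or field was not tested apart from macrophages.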

How the results depend on the processing

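All alternatives were chosen before the data were examined, and none was added afterwards. Without background correction, which gives the same values as the authors' deposited log2 values, the counts were 872 lower for primary neurons against fibroblasts, 78 higher for APNL against fibroblasts, 18 lower for APNL+AuEMF against fibroblasts, 146 higher and 0 lower for APNL+AuEMF against APNL, and 732 and 433 higher for APNL and APNL+AuEMF against primary neurons. In that setting the pan-neuronal median of APNL+AuEMF against fibroblasts was 1.31, and the shares were 29.0% of neuron-high genes higher and 0% of fibroblast-high genes lower with AuEMF. Normexp without control information and with an offset of 50 gave 37 lower for APNL+AuEMF against fibroblasts, a pan-neuronal median of 1.55, 4 lower for APNL+AuEMF against APNL and shares of 33.6% and 0.685%. Both settings leave more background or a larger offset in the signal, which by construction draws folds toward 0. Scaling to a common median gave 67 lower for APNL+AuEMF against fibroblasts, 16 lower for APNL+AuEMF against APNL and shares of 51.7% and 5.79%. A detection p under 0.05 gave 3 lower for APNL against fibroblasts. Detection on both arrays gave 77 higher for APNL and 283 higher for APNL+AuEMF against fibroblasts, pan-neuronal medians of 0.42 and 1.05, and shares of 34.6% and 3.83%, and it turned the median of the ion channel and receptor list in primary neurons against fibroblasts from 1.93 to -0.30. That setting leaves out genes seen on 1 array by construction. No filter and no bounds gave 286 higher and 35 lower for APNL, 749 and 236 for APNL+AuEMF against fibroblasts, and 431 and 105 for APNL+AuEMF against APNL. The mean of a gene's probes gave a pan-neuronal median of 1.26 for APNL+AuEMF against fibroblasts and turned Nsdhl in APNL+AuEMF against primary neurons from 1.04 to -0.0933. A 3-fold threshold, stricter by construction, gave 556 higher and 485 lower for primary neurons, 52 higher for APNL and 229 higher and 1 lower for APNL+AuEMF against fibroblasts, 52 and 0 for APNL+AuEMF against APNL, and 409 and 472 for APNL and 257 and 217 for APNL+AuEMF against primary neurons. Sets at 8-fold gave shares of 65.6% and 15.0%. Apart from the causes named, the cause was not tested. Of 108 recomputed counts 38 moved by over 1.5-fold, and of 120 recomputed medians of the 5 lists fixed as main results 6 did. Of 18 shares 12 left the 95% Wilson interval of their main value, some of them by less than 1.5-fold. Of 1666 other list medians 118 moved, and of 7434 values of single genes 614 moved. No paired analysis was possible because each group has 1 array. Signal over background limits what the arrays can show: genes near the lowest detected values of 7.13 in fibroblasts and 6.36 in primary neurons give only bounds. In simulation 47.1% of genes raised 2-fold were called, but these lie on the 2-fold cut-off itself, so that share does not measure this limit.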

Other observations

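No explanation is offered here, and the groups below were chosen for mention after their values were seen, from lists fixed before the data were examined. Oligodendrocyte precursor gene Olig1 and choroid plexus gene Ttr rose across the arrays in the same order as most pan-neuronal genes. Their shares of the neuron signal in APNL and APNL+AuEMF differed, at 28.4% and 81.6% for Olig1 and 11.9% and 29.8% for Ttr. Those of Olig1 lay near the interferon and cytokine medians (25.1% and 78.6%), and those of Ttr nearer to the neuronal lists (8.02% and 23.3%). Olig1 was at 8.77 in fibroblasts, 10.85 in APNL, 12.13 in APNL+AuEMF and 12.39 in primary neurons, and Ttr at 5.66 (not detected), 9.87, 11.15 and 12.88. Other genes of the oligodendrocyte list did not go with Olig1, since Cldn11 was at 10.37, 10.22, 9.27 and 6.98. Endothelial genes were lower in primary neurons than in fibroblasts in 3 of 5, with Flt1, a receptor gene for vascular growth factor, at -2.86. In APNL+AuEMF against fibroblasts 2 of 5 were lower, Emcn at -1.15 and Tek at -1.03, with a list median of -0.61. The chromatin remodelling list had 5 higher and 2 lower of 19 in primary neurons against fibroblasts, including Chd5, a neuronal chromodomain gene, at least 8.21-fold. It had none higher or lower in APNL or in APNL+AuEMF against fibroblasts. Lysosome genes were lower in 4 of 18 in primary neurons, with Ctsk, cathepsin K, at -1.77, and the macrophage-rich cathepsin gene Ctss was at least 2.46-fold higher in APNL+AuEMF than in APNL. Cdkn2a, a cell cycle inhibitor gene, was at least 6.58-fold higher in primary neurons and at least 5.19-fold in APNL+AuEMF than in fibroblasts.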
